A study of Mus musculus with 8 samples.

How the data were processed

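Total RNA from the distal colon of 8 mouse samples, 4 from enriched (EE) and 4 from conventional (NE) housing, was made into ribosomal RNA-depleted, strand-preserving libraries and read as single ends of 50 bases on an Illumina HiSeq, per the labels' protocols. Per the submitters' processing notes the tools included Novoalign 2.08.01 and DESeq 1.14.0 with genome build mm10, and the labels' protocols cite a negative binomial model and the USeq tools. The annotation, the counting program and whether counting used the strand are not given in the sources used here, so a gene and its antisense partner, and near-identical copies such as the globin genes, may share reads.

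The authors deposited one table of 16130 genes with a raw read count per gene for each of the 8 libraries, taken here as whole-number counts because all values are whole and library totals differ. The smallest total over the 8 libraries was 12 counts, so genes with fewer counts do not appear in the table. The deposited table also holds, per the file headers, a log2 fold change and an FDR (an adjusted p-value) from the authors' own comparison; the headers do not say which group is the numerator. Its log2 fold changes reached at most 1.90 in size. Groups and replicate numbers were taken from the sample titles, which match the column names. Symbols are those of the table, and 145 entries without a usable symbol were kept under their Ensembl identifiers. Of the 16130 identifiers, 15948 were found in GENCODE M21, whose GRCm38 coordinates are the same build as mm10.

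Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were left out with filterByExpr, which kept 14311 genes, libraries were scaled by TMM, and EE was compared with NE by the robust quasi-likelihood test with Benjamini-Hochberg adjustment and a threshold of 0.05. No covariate was used. CPM are the values of edgeR's cpm function, counts scaled by the TMM-scaled library size, and log2 CPM used a prior count of 2. The standard error of a log2 fold change is its size divided by the square root of the quasi-likelihood F. Library totals between 4735764 and 10586851 counts set the precision of low genes, and the biological coefficient of variation was 0.219.

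A set of 43 gene lists of colon cell types, the subjects of the series title and common responses was fixed before the data were examined. One, of sex-linked genes, was read per library, and 42 were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, each adjusted over the 42 lists. Of the 601 list entries 506 were tested, and some genes stand in more than one list. A list's value in a library is the median over members of log2 CPM minus the gene's mean over the 8 libraries; these medians were compared by two-sided exact permutation tests, whose smallest possible p is 0.0286. Principal components used the 500 most variable genes.

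The rule for named genes, also fixed beforehand, took Tcf7l2, Apc, Igha, Pdgfrb and Pigr; the 10 highest and 10 lowest fold changes among annotated genes past the threshold with groups that do not overlap and at least 1 CPM, or, since none passed, the 10 genes with the smallest p; and in each list up to 4 members past the threshold or, since none passed, up to 2 with the smallest p in each list discussed. Of the genes this rule took, 2 are not reported here. Genes named from the authors' deposited table were chosen after their values were seen, by the second part of this rule applied to that table.

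Alternatives planned beforehand were DESeq2 (version 1.42.0), limma-voom, RLE and upper-quartile scaling, no filter or a filter at 1 CPM in at least 4 libraries, the replicate number as a block, each library left out in turn, immunoglobulin genes left out, thresholds of 0.1 and 0.01, an estimated correlation for the lists, and all tested genes for the principal components. A pseudocount was planned only for normalized values and was not needed. DESeq2 with the dispersion of the fitted trend for every gene, and fits without EE 4 by that model and with an estimated correlation, were added after the data were seen. DESeq2 gave no adjusted p for 22 genes, which were left as missing.

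The tests were checked on counts simulated for EE against NE from the real means, library sizes and dispersions of 14311 genes, with 100 genes changed 2-fold and 100 changed 4-fold. The edgeR test recovered 54 of the 2-fold and 90 of the 4-fold genes with 12 false calls, limma-voom 50 and 88 with 12, DESeq2 70 and 94 with 36, and DESeq2 with the trend dispersion 68 and 94 with 99. A simulated list of 20 genes raised 2-fold was called by camera with both correlations. The simulated genes were independent of each other, so the simulation does not measure how often camera calls unchanged lists whose genes move together.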

Results

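RNA from the distal colon of mice that carried the ApcMin allele and a heterozygous Tcf4 allele was sequenced to compare 2 kinds of housing. ApcMin is a truncating allele of Apc, the tumour suppressor that limits Wnt signalling, and animals that carry it grow intestinal adenomas. In Wnt work TCF4 is the usual name of the product of Tcf7l2, the transcription factor through which the pathway acts in the gut. One group had lived for 4 months in enriched housing (EE, n = 4) and the other in conventional, non-enriched housing (NE, n = 4). The series title names pericytes, IgA, wound repair and lifespan as the subjects of the study, and the comparison addresses which transcripts differ with housing. Counts assigned to the 16130 genes in the table summed to 6600039, 7087191, 10586851 and 6120185 in NE 1 to NE 4 and to 4735764, 5430664, 6266902 and 6070240 in EE 1 to EE 4. The labels do not say whether each library came from a separate animal, so every p-value measures the spread between these samples. All 8 libraries carried Y-linked transcripts, with 516 to 943 counts of Ddx3y and 0 to 10 counts of Xist.

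The columns labelled EE and NE have a direction that the files leave open. The fold changes in the authors' deposited table were positive where the NE columns were higher, and for 97.8% of the genes tested here their sign was opposite to EE minus NE. A ratio taken as NE over EE would give these signs, and so would exchanged column names. Below, EE and NE mean the libraries labelled so, and all fold changes are EE minus NE unless the deposited table is named.

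The first question was whether housing separated the libraries. Library EE 4 stood far from the other 7, at 46.3 on the first principal component of log2 CPM (counts scaled by library size) against −14.2 to 6.36 for the rest. That component held 58.7% of the variance of the 500 most variable genes. The groups overlapped on it (two-sided exact permutation test, p = 0.0857, n = 4 and 4) and on the second component, which held 16.0% (exact permutation p = 0.886). Library EE 2 lay among the NE libraries at −10.4. Spearman correlation between libraries over tested genes ranged from 0.934 for NE 1 with EE 4 to 0.991 for NE 2 with NE 3, and no pair of libraries was close enough to be one library deposited under 2 names (chi-square per degree of freedom of at least 7.46).

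**Figure D1:**
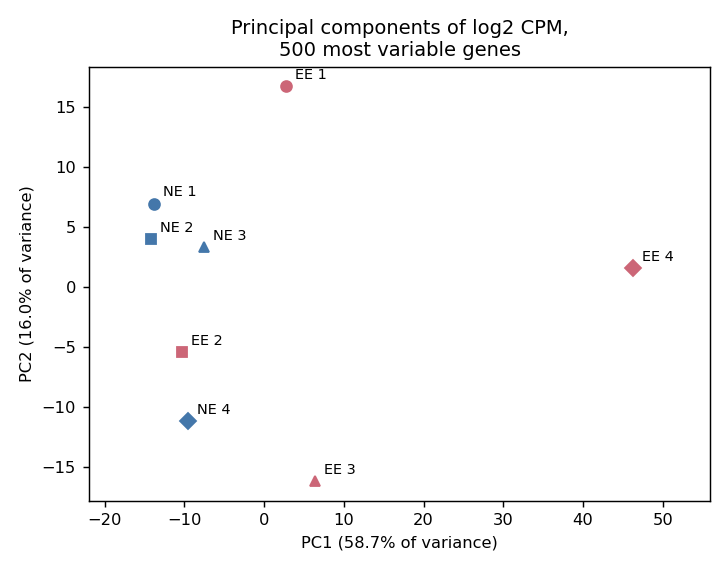
Principal components of log2 CPM over the 500 most variable genes, one point per library (blue NE, red EE; the symbol marks the replicate number). EE 4 lies at 46.3 on the first axis and EE 2 lies at −10.4, within the range of the NE libraries.

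Of the 10 genes with the smallest p, 8 stood at higher values in the EE libraries and 2 at lower values. Rrm2, the small subunit of ribonucleotide reductase (chromosome 12, 24708241 to 24714146 on GRCm38), was at 28.4 ± 4.74 CPM in NE and 50.2 ± 5.09 CPM in EE (SD, n = 4 each), a log2 fold change of 0.83 with a standard error of 0.14. Ncl, which encodes the nucleolar protein nucleolin, was at 226 ± 14.2 and 357 ± 55.2 CPM. The calcium-binding protein gene S100a11 was at 40.2 ± 6.58 and 70.6 ± 15 CPM. Dusp4, a phosphatase induced by ERK signalling, was at 34.9 ± 3.51 and 62.6 ± 15.3 CPM, and Macc1, a regulator of Met, at 20.95 ± 1.27 and 33.4 ± 3.53 CPM. Lpcat4, an acyltransferase of membrane lipids, and Itgb8, an integrin subunit, had log2 fold changes of 0.77 (SE 0.17) and 0.66 (SE 0.14). At lower values in EE were Sycn, the secretory granule protein syncollin (chromosome 7, 28540885 to 28542209), with 234 ± 43.9 CPM in NE and 121 ± 21 CPM in EE, and Npy4r, a receptor of the pancreatic polypeptide family, with 8.31 ± 1.46 and 3.34 ± 0.784 CPM. In these 10 genes the 4 EE values did not overlap the 4 NE values. Choosing genes by the smallest p favours such a separation, so it gives no added support.

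None of these differences passed the test over all genes. Of 14311 genes tested with edgeR's quasi-likelihood test, 0 had a Benjamini-Hochberg adjusted p under 0.05, and the lowest was 0.520, which the 10 genes share. At an unadjusted p under 0.05 there were 1357 genes, 820 higher and 537 lower in EE, where 716 are expected with no change. That count ran from 665 without NE 1 to 2745 without EE 2, and limma-voom gave 736 higher and 825 lower. The 4 EE values did not overlap the 4 NE values in 700 genes (4.89%), of which 411 were higher in EE, and chance alone gives 2.86%. DESeq2 called 16 genes (10 higher and 6 lower in EE), among them Rrm2, Sycn, Ncl, Hbb-bt and the brush border disaccharidase Sis, and limma-voom called 0. Without EE 2 edgeR called 1 gene, the amino acid transporter Slc38a4.

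**Figure D2:**
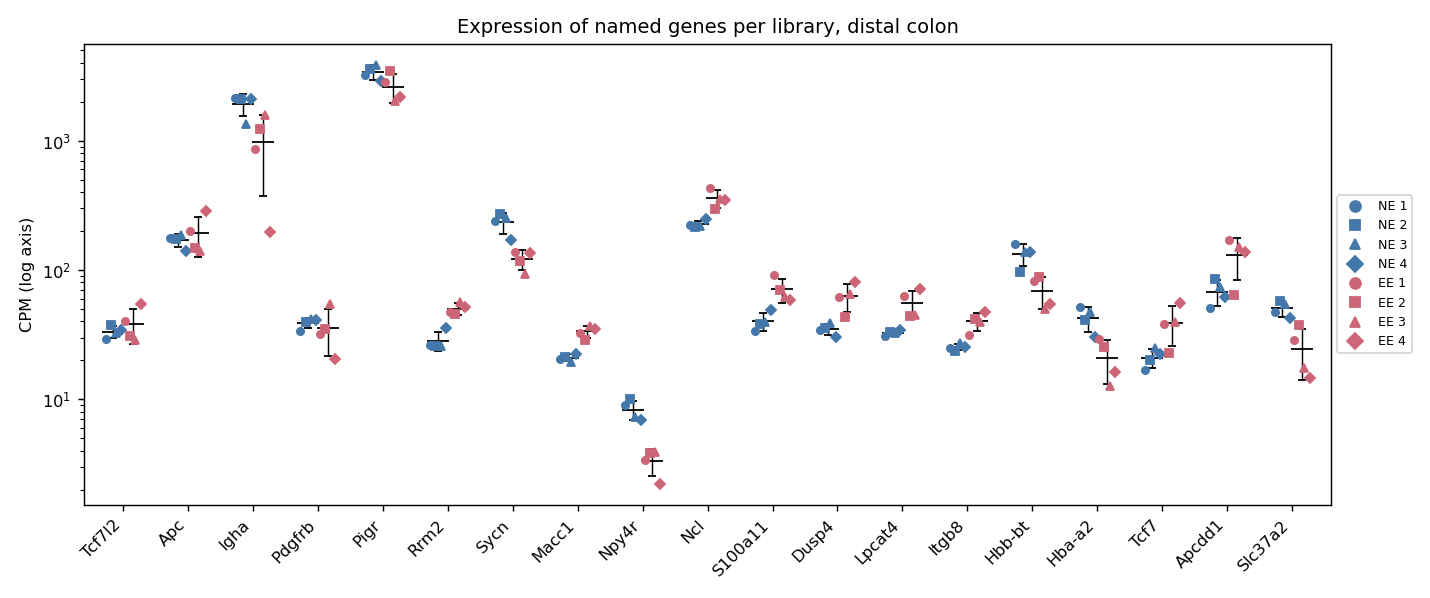
CPM on a log axis of genes named by the genotype or the title (Tcf7l2 to Pigr), 9 of the 10 genes with the smallest p (Rrm2 to Itgb8) and members of the red blood cell, Wnt and colonocyte lists (Hbb-bt to Slc37a2), one point per library with the group mean and SD as bars (n = 4 each). Rrm2 lies at 25.9 to 35.5 CPM in NE and 45.6 to 57.0 CPM in EE, and Igha in EE 4 lies at 196.6 CPM.

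The 42 gene lists fixed beforehand gave a wider view. With camera at a preset inter-gene correlation of 0.01, 23 lists had an adjusted p under 0.05, 4 of them higher and 19 lower in EE. Genes in one list moved together from library to library, and with an estimated correlation 0 lists passed (lowest adjusted p = 0.444). With fry, which asks whether a list's genes move one way without comparing them with other genes, 0 passed (lowest adjusted p = 0.205). The directions below are therefore those of camera at the preset correlation, and all gene members are given as values because none passed over all genes. Without EE 4, 14 of the 23 lists still passed at the preset correlation and 0 with an estimated one (lowest adjusted p = 0.600).

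Cell division genes were higher in EE. All 18 tested members had a positive log2 fold change, with a median of 0.36 (camera adjusted p = 1.26e-08, and adjusted p = 0.444 with an estimated correlation), and 0 passed when adjusted over the list alone. The helicase subunit Mcm7 was at 51.3 ± 3.92 CPM in NE and 73.3 ± 14.1 CPM in EE, and the mitotic kinase Aurkb at 25.5 ± 0.938 and 34.4 ± 3.82 CPM. The list median lay above every NE library in each EE library (two-sided exact permutation test on the 8 library medians, p = 0.0286, the smallest that 4 against 4 allows, and 0.300 after adjustment over the 42 lists). Without EE 4 the list's median log2 fold change was 0.30.

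Wnt target and crypt stem cell genes were also higher, in 15 of 16 members, with a median log2 fold change of 0.79 (camera adjusted p = 2.08e-08, and adjusted p = 0.444 with an estimated correlation). Adjusted over the list alone, 8 members passed. Tcf7, a transcription factor of the pathway, was at 20.98 ± 3.47 CPM in NE and 39.1 ± 13.4 CPM in EE. Apcdd1, a Wnt inhibitor that is itself a target, was at 68.0 ± 15 and 130 ± 46.2 CPM. The feedback inhibitor Axin2 ran from 106.9 to 163.3 CPM in the NE libraries and stood at 237.4, 123.4, 263.2 and 377.3 CPM in EE 1 to EE 4. EE 2 therefore lay within the NE range, its list median was −0.50 against −0.64 to −0.14 in NE, and the groups overlapped (exact permutation p = 0.114). Without EE 4 the median log2 fold change was 0.54.

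Genes of mature epithelial cells were lower in EE. All 12 colonocyte genes had negative log2 fold changes (median −0.39, camera adjusted p = 3.85e-04), as had all 12 goblet cell genes (median −0.43, adjusted p = 2.86e-05) and all 7 enteroendocrine genes (median −0.74, adjusted p = 8.85e-05). For each of the 3 lists the adjusted p was 0.444 with an estimated correlation, and without EE 4 the medians were −0.22, −0.43 and −0.58. Slc37a2, a sugar phosphate transporter, was at 50.4 ± 7.0 CPM in NE and 24.5 ± 10.5 CPM in EE and was the 1 colonocyte gene to pass adjusted over the list alone. The water channel Aqp8 was at 231 ± 40.6 and 140 ± 64.6 CPM. Agr2, a protein disulfide isomerase needed for mucin, was at 1849 ± 259 and 1290 ± 333 CPM, and Atoh1, the factor that sets the secretory fate, at 67.3 ± 12.4 and 47.8 ± 13.6 CPM. The granins Chgb and Chga of hormone-secreting cells were at 102 ± 23.7 and 49.9 ± 9.79 CPM in NE and 59.2 ± 24.9 and 30.1 ± 12.4 CPM in EE. The enteroendocrine medians did not overlap between the groups (exact permutation p = 0.0286, and 0.300 after adjustment over the 42 lists), and the lowest values of all 3 lists were in EE 3 and EE 4.

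Metabolic and nuclear receptor lists were lower with them. Xenobiotic and bile acid genes had a median log2 fold change of −0.45, with 13 of 15 lower (camera adjusted p = 2.38e-04, and adjusted p = 0.444 with an estimated correlation), and −0.27 without EE 4. Sult1a1, a sulfotransferase, was at 174 ± 59.8 CPM in NE and 100 ± 49.3 CPM in EE, while the cytochrome Cyp2b10 went the other way, with 5.62 ± 1.29 and 8.69 ± 2.55 CPM. Of 37 nuclear receptors 28 were lower (median −0.29, adjusted p = 0.00227, and adjusted p = 0.444 with an estimated correlation; median −0.19 without EE 4), with Ppara at 16.6 ± 2.95 and 8.84 ± 4.28 CPM and the clock repressor Nr1d1 at 39.3 ± 5.75 and 25.9 ± 6.61 CPM. Fatty acid oxidation and PPAR target genes had a median of −0.17 (adjusted p = 0.0197, and adjusted p = 0.545 with an estimated correlation), a call that ended without NE 1, EE 3 or EE 4 (adjusted p 0.0534, 0.153 and 0.354). The mitochondrial enzymes Acaa2 and Acadm were at 133 ± 17.0 and 129 ± 8.50 CPM in NE and 93.9 ± 25.3 and 101 ± 27 CPM in EE.

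Wound repair genes, a subject of the series title, were higher in EE in 13 of 14 members (median log2 fold change 0.35, camera adjusted p = 6.02e-04, and adjusted p = 0.444 with an estimated correlation). The epidermal growth factor receptor ligands Hbegf and Areg were at 16.8 ± 4.18 and 22.7 ± 9.41 CPM in NE and 27.3 ± 2.20 and 35.7 ± 6.09 CPM in EE, and Hbegf was the 1 member to pass adjusted over the list alone. EE 1 lay with the NE libraries, at a list median of −0.24. Without EE 4 the median was 0.43. Immediate early genes were higher in 8 of 12 members (median 0.20, adjusted p = 0.0427, and adjusted p = 0.444 with an estimated correlation). Egr1 was at 15.6 ± 1.77 CPM in NE and 24.9 ± 7.20 CPM in EE, and Jun at 168 ± 25.5 and 219 ± 49.2 CPM. This call ended when any one of NE 3, NE 4, EE 1, EE 2 or EE 4 was left out (adjusted p 0.127, 0.0766, 0.0533, 0.0770 and 0.106).

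Pericyte genes, another subject of the title, were lower in the EE libraries in 9 of 10 members (median log2 fold change −0.35, camera adjusted p = 0.00736, and adjusted p = 0.444 with an estimated correlation). The call ended without library EE 4, where the median log2 fold change was −0.15 and camera's adjusted p at the preset correlation 0.224. The list median was −1.39 in EE 4, −0.02 in EE 1, 0.46 in EE 2 and 0.04 in EE 3, against 0.17 to 0.34 in NE. EE 1 and EE 3 therefore also lay below every NE library. The channel subunit Abcc9 was at 42.6 ± 6.81 CPM in NE and 26.1 ± 13.5 CPM in EE, and the surface protein Cd248 at 5.25 ± 1.92 and 2.97 ± 1.69 CPM. Pdgfrb, the receptor that marks pericytes (chromosome 18, 61045150 to 61085061), was at 39.1 ± 3.74 and 35.5 ± 14 CPM, a log2 fold change of −0.14 (SE 0.24, edgeR adjusted p = 0.838) that was 0.07 without EE 4.

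Plasma cell and immunoglobulin genes were lower in EE in 13 of 15 members (median −0.67, camera adjusted p = 5.63e-04, and adjusted p = 0.444 with an estimated correlation). Igha, the constant region of IgA (chromosome 12, 113254830 to 113260236, minus strand), was at 1926 ± 381 CPM in NE and 971 ± 595 CPM in EE, a log2 fold change of −0.99 (SE 0.48, edgeR adjusted p = 0.522). Its values in EE 1 to EE 4 were 869, 1225, 1593 and 196.6 CPM, against 1356 to 2151 CPM in NE. Xbp1, which drives antibody secretion, was at 324 ± 18.8 and 263 ± 23.9 CPM, and Derl3 at 3.97 ± 1.58 and 1.89 ± 0.693 CPM. In EE 4 Xbp1 (254.1 CPM) and Derl3 (1.585 CPM) lay within the range of the other EE libraries, as did Sdc1, Tnfrsf13b and Txndc5. Prdm1 lay above that range. Igkc (75.78 CPM against 366.3 to 727.2), Jchain (107.5 against 514.5 to 1047) and Mzb1 (1.903 against 8.069 to 18.43) lay below it, like Igha. So did Ighm, Iglc2, Irf4, Pou2af1 and, narrowly, Fkbp11. Pigr, the receptor that carries IgA across the epithelium (chromosome 1, 130826684 to 130852249), was at 3389 ± 433 and 2623 ± 652 CPM, a log2 fold change of −0.37 (SE 0.20, adjusted p = 0.544). Without EE 4 the median of the list was −0.33 and camera's adjusted p at the preset correlation was 0.00355, and with an estimated one the list did not pass.

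Red blood cell genes were lower in EE, and their list median lay below every NE library in each EE library. All 6 tested members were lower in EE (median log2 fold change −0.91, camera adjusted p = 1.26e-08, and adjusted p = 0.444 with an estimated correlation), and 5 passed adjusted over the list alone. The beta globin gene Hbb-bt was at 133 ± 25.7 CPM in NE and 68.5 ± 19.0 CPM in EE, and the alpha globin gene Hba-a2 at 42.5 ± 9.34 and 20.8 ± 7.62 CPM. Globin genes have near-identical copies, so the split of reads between copies is uncertain. On the 8 library medians the two-sided exact permutation test gave p = 0.0286 (0.300 after adjustment over the 42 lists), and without EE 4 the median was −0.78.

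The smooth muscle, enteric glia, T cell and B cell lists were lower in EE as well, and EE 4 had the lowest median in each of these 4. All 12 smooth muscle genes had negative values (median −0.78, camera adjusted p = 4.88e-07, and adjusted p = 0.444 with an estimated correlation), with the contraction genes Mylk at 479 ± 112 CPM in NE and 282 ± 144 CPM in EE and Lmod1 at 42.3 ± 9.19 and 21.9 ± 14.1 CPM. The list median in EE 4 was −2.33, against −0.48 to 0.39 in the other EE libraries. Enteric glia (5 of 5 lower, median −1.02), T cells (12 of 14, median −0.56) and B cells (10 of 11, median −0.78) had adjusted p of 5.43e-04, 5.58e-04 and 2.38e-04, and of 0.444 each with an estimated correlation. Among their members Cdh19 and Gpr37l1 of glia were at 6.12 ± 1.99 and 2.55 ± 0.355 CPM in NE and 2.32 ± 1.75 and 1.06 ± 0.658 CPM in EE. Cd8a of T cells was at 5.95 ± 1.73 CPM in NE and 2.57 ± 0.853 CPM in EE. Cd22 and Cxcr5 of B cells were at 4.61 ± 0.654 and 2.68 ± 0.631 CPM in NE and 2.06 ± 0.943 and 1.56 ± 0.846 CPM in EE. Without EE 4 these 4 lists passed with smaller medians, at −0.45 for smooth muscle, −0.69 for glia, −0.27 for T cells and −0.42 for B cells. With an estimated correlation none of them passed without EE 4 (lowest adjusted p of any list 0.600).

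The lists of enteric neurons, fat cells, MHC class II, fibroblasts and matrix, macrophages and blood vessel endothelium had median log2 fold changes of −0.54, −0.53, −0.49, −0.22, −0.29 and −0.34, with camera adjusted p between 0.00209 and 0.0177, and between 0.444 and 0.556 with an estimated correlation. Without EE 4 the medians were −0.20, −0.25, −0.19, −0.06, −0.03 and −0.05, and none of the 6 passed (adjusted p 0.0550 to 0.804). The macrophage call also ended without NE 4 or EE 1 (adjusted p 0.110 and 0.0948) and the endothelial call without NE 4 (adjusted p 0.0686). Nos1, the neuronal nitric oxide synthase, was at 11.05 ± 3.64 CPM in NE and 5.10 ± 3.41 CPM in EE, the lipid droplet gene Plin4 at 23.2 ± 7.20 and 11.2 ± 7.19 CPM, and the class II transactivator Ciita at 20.7 ± 6.28 and 12.1 ± 4.44 CPM. Mertk of macrophages was at 43.1 ± 3.49 and 30.9 ± 8.39 CPM, and Tie1 of endothelium at 11.5 ± 2.05 and 8.30 ± 2.63 CPM. Fn1, fibronectin, differed in sign from its list, with 770 ± 53.6 CPM in NE and 940 ± 204 CPM in EE.

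**Figure D3:**
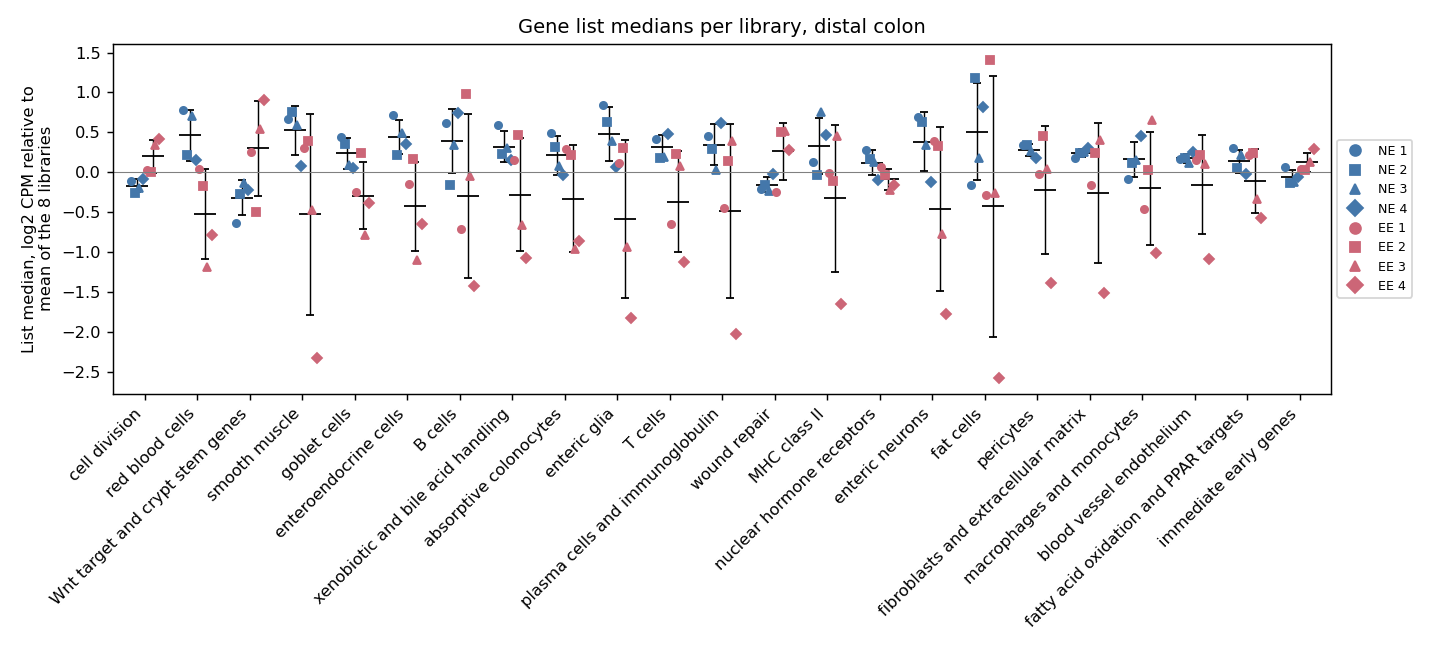
Median over each gene list of log2 CPM relative to the gene's mean of the 8 libraries, for the 23 lists that camera called at the preset correlation, one point per library with the group mean and SD as bars (blue NE, red EE; n = 4 each). Cell division, red blood cell and enteroendocrine medians do not overlap between the groups, and EE 4 lies at −2.33 for smooth muscle and −2.58 for fat cells.

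The remaining 19 lists did not pass camera (adjusted p 0.0663 to 0.932). They were lymphatic endothelium, the unfolded protein response, tuft cells, organised lymphoid tissue, eosinophils, the interferon response, skeletal muscle, the circadian clock, squamous epithelium, mitochondrially encoded mRNA, cholesterol synthesis, inflammatory mediators, ribosomal proteins, tight junctions, neutrophils, the hypoxia response, antimicrobial defence, mast cells and glucocorticoid targets. For neutrophils and mast cells the sign of the median (−0.06 and 0.10) differed from that of the test. The genes of both alleles that the animals carried were measured too. Apc (chromosome 18, 34220924 to 34322552) was at 169 ± 19.7 CPM in NE and 192 ± 65.7 CPM in EE (log2 fold change 0.19, SE 0.21, edgeR adjusted p = 0.741), and Tcf7l2 (chromosome 19, 55741820 to 55933654) at 33.4 ± 3.59 and 38.4 ± 11.8 CPM (0.20, SE 0.20, adjusted p = 0.695). Both differences had the other sign without EE 4, at −0.06 and −0.01. Per the labels all animals carried the same alleles, so these counts do not check the labels.

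The authors' deposited table gave its own comparison of the same libraries, with 386 genes at an FDR under 0.05. Of these, 173 were higher in the EE columns and 213 in the NE columns. In the authors' deposited table, 10 of the 16 Wnt and stem cell genes were called higher in EE (Lgr5, Axin2, Rnf43, Znrf3, Nkd1, Notum, Lef1, Tcf7, Sp5 and Apcdd1) and 11 of 12 smooth muscle genes, 5 of 7 red blood cell genes, 4 of 12 colonocyte genes and 3 of 10 enteroendocrine genes were called higher in NE. The authors' deposited table called 0 of 18 cell division genes, 0 of 13 B cell, 0 of 18 T cell, 0 of 14 macrophage, 0 of 15 endothelial and 0 of 12 immediate early genes in either direction. The authors' deposited table also called the immunoglobulin genes Igha and Igkc, the joining chain gene Jchain, and the pericyte genes Rgs5 and Abcc9 higher in NE, with a log2 fold change of 1.30 (NE over EE) and an FDR of 2.80e-04 for Igha. Of the 386 calls in the authors' deposited table, 352 were tested here and 47 of those (13.4%) had EE values that did not overlap the NE values. Among annotated genes of that kind, chosen after the values were seen, the deposited table had its most negative log2 fold changes for Gdf11 (−0.86), Evx1os (−0.78), the aldehyde oxidase Aox4 (−0.76) and the ERK-responsive factor Etv5 (−0.74), all higher in EE. Its most positive ones were for the matrix gene Hmcn2 (1.37), H2-Eb1 of MHC class II (1.06), Abca8a (1.06) and Hba-a1 (0.96). The clock output gene Dbp, at 0.83 in the authors' deposited table, stood at 18.4 to 37.0 CPM in NE and 8.61 to 15.9 CPM in EE.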

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

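The counts over other splits and the camera fits at the preset correlation without EE 4 were planned, while the other tests in this part, and the use of those fits to weigh EE 4 alone, were chosen after the result was seen.

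Within a group of 4 libraries, 1 value lay far from the other 3, by Dixon's ratio of the gap to the range, in 11 of 236 groups of values looked at, where chance alone gives about 12. In 4 of them the library was EE 4. Its list medians were −1.09 for blood vessel endothelium (ratio 0.916, other EE libraries 0.10 to 0.21), −1.35 for lymphatic endothelium (ratio 0.887, others 0.04 to 0.22) and −0.51 for mast cells (ratio 0.839, others 0.16 to 0.28), and its Egr1 level was 35.7 CPM (ratio 0.879, others 20.7 to 22.5). Among NE libraries, the interferon list was at 0.40 in NE 2 (ratio 0.849) and the squamous epithelium list at 0.20 in NE 4 (ratio 0.913). Igha was at 1356 CPM in NE 3 (ratio 0.922, others 2089 to 2151), and H2-Eb1 was at 199.7 CPM in the same library (ratio 0.942). Rrm2 was at 35.5 CPM in NE 4 (ratio 0.988, others 25.9 to 26.1) and Acaa2 at 157.9 CPM in NE 1 (ratio 0.843). Khdc1a was at 21.02 CPM in EE 1 (ratio 0.908, others 13.01 to 13.75).

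The first pattern is the lower level of non-epithelial lists in the EE libraries, and the question is whether library EE 4 alone gives it. It may for the enteric neuron, fibroblast, endothelial, macrophage, MHC class II and fat lists, since 0 of the 6 passed camera without EE 4. In some of these 6, though, another EE library lay below every NE library by more than the NE SD. EE 3 was at −0.77 for enteric neurons, and EE 1 at −0.47 for macrophages and −0.17 for fibroblasts. The lowest NE values were −0.13, −0.08 and 0.18. For the endothelial, MHC class II and fat lists no EE library but EE 4 lay that far below NE. The red blood cell list argues against EE 4 alone, since the other 3 EE libraries also lay below every NE library, 2 of them by more than the NE SD. EE 1, EE 2 and EE 3 were at 0.045, −0.176 and −1.19, against a lowest NE value of 0.155 and an NE SD of 0.323. EE 2 thus met that margin only narrowly. Camera called that list without EE 4 at the preset correlation, and no list with an estimated one (lowest adjusted p 0.600). Whether EE 4 alone gives the pattern cannot be decided for pericytes, where 2 of the other 3 EE libraries lay that far below NE but the call ended without EE 4. The same holds for the lymphoid lists (B, T and plasma cells), of which 3 passed without EE 4 at the preset correlation, and for smooth muscle and glia, of which 2 did. In each of these last 5 lists 1 of the other EE libraries lay that far below NE. Within EE 4 the 13 non-epithelial list medians ran from −0.89 for red blood cells to −2.67 for smooth muscle and −2.94 for fat against the other 7 libraries. That spread was wider than random lists give (permutation p = 0.0016). The permutation moved genes between lists as if they were independent, while genes in one list moved together. It therefore cannot decide whether all non-epithelial tissue was lowered alike. That, a piece taken at another depth of the wall and an effect of housing all stay open.

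The second pattern is the higher level of cell division and Wnt lists in the EE libraries. EE 4 alone is argued against for cell division, where 3 of the other 3 EE libraries lay above every NE library by more than the NE SD, and for Wnt targets, where 2 did, EE 1 at 0.26 and EE 3 at 0.54 against at most −0.14 in NE. Without EE 4 the adjusted p of the Wnt list was 1.18e-05 by camera at the preset correlation, no list passed with an estimated one (lowest adjusted p 0.600), and EE 2 lay among the NE libraries. More adenoma or crypt tissue in some pieces is a candidate explanation for the Wnt list, whose medians over the 8 libraries moved against those of colonocytes (Pearson r = −0.847, exact permutation p = 0.0117; Spearman rho = −0.762, exact permutation p = 0.0368) but as much against smooth muscle (r = −0.848, exact permutation p = 0.00531; rho = −0.786, exact permutation p = 0.0279) and with cell division (r = 0.836, exact permutation p = 0.0123; rho = 0.690, exact permutation p = 0.0694). Adjusted over these 3 relations each r had p = 0.0123 and the rho p = 0.0551, 0.0551 and 0.0694, and without EE 3 and EE 4 r was −0.318, −0.367 and 0.222, so the relations rest on those libraries, a piece with less wall muscle could also have a higher Wnt median, and the explanation cannot be told apart from that or from an effect of housing.

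The third pattern is the direction of the deposited fold changes. For 97.81% of genes the sign was opposite to EE minus NE, which exchanged column names could give and a ratio taken as NE over EE would give equally, so the explanations cannot be told apart from these files. Every direction given for EE and NE depends on the column names being right.

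The 8 libraries can be split into 4 and 4 in 35 ways, the real one included, and chance could not be excluded for the 4 counts above 0. Each number of splits below includes the real one. For edgeR's 0 genes past the threshold the comparison decides nothing, since 35 of 35 splits must give at least 0 (highest other 1). At an unadjusted p under 0.05, 6 of the 35 gave at least the real 1357 genes (highest other 2308). With camera, 7 gave at least the real 23 lists (highest other 28). With DESeq2, 7 gave at least the real 16 genes (highest other 378), and with its trend dispersion 5 gave at least the real 308 (highest other 759). The highest counts by both DESeq2 fits and at the unadjusted p came from NE 1, NE 2, NE 3 and EE 2 against the rest. The highest camera count came from another split, NE 1, EE 1, EE 3 and EE 4 against the rest. Some split must give the highest count, and whether these splits reflect a structure of the samples was not tested.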

How the results depend on the processing

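Fits with the trend dispersion, and the estimated correlation without EE 4, were chosen after the data were seen. The count of 0 genes held under limma-voom, RLE and upper-quartile scaling, both other filters and removal of immunoglobulin genes. At thresholds of 0.1 and 0.01 the count was also 0, which edgeR's lowest adjusted p of 0.520 fixed in advance. DESeq2 called 16 genes, and leaving out each library in turn gave 0 to 1, the 1 being without EE 2. DESeq2 with the trend dispersion for every gene called 308 genes (141 higher and 167 lower in EE) and without EE 4 called 109. Of the 308, 302 were among the 386 calls of the authors' deposited table, against 11 of DESeq2's 16, so calls of that kind may come from a dispersion that ignores each gene's own spread; in the simulation that fit made 99 false calls against 36 for DESeq2. Genes at an unadjusted p under 0.05 ranged from 665 without NE 1 to 2745 without EE 2, around 1357, and limma-voom split its 1561 into 736 higher and 825 lower. The 23 lists became 0 with an estimated correlation (0 also without EE 4) and 15 to 25 when each library was left out, with 15 without EE 4. The cause of these changes was not tested. The principal component test gave p = 0.0857 by exact permutation with all tested genes as well. The log2 fold change of 3 named genes reversed in sign without EE replicate 4. It ranged from −0.01047 (without EE replicate 4) to 0.3389 (without EE replicate 3) for Tcf7l2, from −0.05807 (without EE replicate 4) to 0.3245 (without EE replicate 3) for Apc, and from −0.4179 (without EE replicate 3) to 0.06748 (without EE replicate 4) for Pdgfrb, and the other named genes kept their sign in every alternative run. Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at 0.254, 0.0101, −0.18 and −0.0374, and not every library correlated best with its own number. With the replicate block 0 genes and 26 lists passed, and 634 genes were higher and 772 lower at an unadjusted p under 0.05. Low counts limit genes such as Cd22 and Gpr37l1, at a few CPM.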

Other observations

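The values and tests in this part were chosen after the data were seen, except the test of Dbp within its list, which was planned.

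Clock genes differed between libraries of the same group. Per3 was at 44.4, 54.3, 32.1 and 31.7 CPM in NE 1 to NE 4 and at 54.1, 27.4, 18.9 and 56.8 CPM in EE 1 to EE 4, and Per2 was at 36.5, 42.7, 21.6 and 23.9 CPM and at 42.04, 21.05, 10.58 and 45.82 CPM. Dbp, which is driven by the same clock, was at 37.0, 36.3, 18.4 and 19.9 CPM in NE and at 14.9, 15.9, 8.61 and 10.5 CPM in EE, so EE 1 and EE 4 had high Per3 and Per2 with low Dbp. Dbp was the 1 clock gene of 17 to pass adjusted over the list alone.

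Digestive enzymes of the exocrine pancreas were read almost only in EE 2. Pnlip had 138 counts there against at most 2 in any other library, Cel 96 against 4, Ctrb1 91 against 4, Cpa1 80 against 2, Cpb1 78 against 6 and Cela2a 77 against 1. In the authors' deposited table Pnlip had an FDR of 1.55e-14. The predicted gene Gm9765 had 844 counts in NE 2 and at most 1 elsewhere, with an FDR of 9.39e-56 in the authors' deposited table. Of the 386 calls in the authors' deposited table, 33 had over 50% of their summed CPM in 1 library, in EE 2 for 10 of them.

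Some genes were on in some libraries and far lower in the rest. A gap of at least 2 in log2 CPM with 2 to 6 libraries on was found for 13 genes other than immunoglobulin genes. Of these, 10 were on only in some libraries of 1 housing group, and 3 (Hoxd12, Mptx1 and Gm10263) in libraries of both. Mptx1 was not near 0 where it was low, at 84.09 CPM in EE 3 and 43.26 CPM in EE 4. Ifi202b, an interferon-inducible gene, was at 17.67 and 24.04 CPM in NE 2 and NE 3 and at most 0.212 CPM elsewhere. The pseudogenes Glns-ps1 and Gm7658 were on only in NE 1 and NE 2 (at least 13.5 and 10.7 CPM), and Gm10263 was on in NE 4, EE 2, EE 3 and EE 4 at 43.9 to 64.7 CPM against at most 0.637 CPM in the others. St6galnac1 (chromosome 11, 116765025 to 116775507), the antisense gene BC018473 (116752167 to 116759373) and the pseudogene Gm11735 (116739062 to 116749833) were on only in EE 3 and EE 4, St6galnac1 at 9.11 and 16.6 CPM against at most 0.212 CPM. A candidate explanation is a strain variant shared by those animals in a mixed background. Genes with the same libraries on lay within 1 Mb of each other in 3 pairs. No draw of 10000 random placements gave as many (permutation p = 1e-04, the smallest the draws can give). But all 3 pairs come from the chromosome 11 stretch, where BC018473 lies on the plus strand and St6galnac1 and Gm11735 on the minus strand. One transcript read through these neighbouring genes could also give all 3 pairs, but only if counting ignored the strand, which is not known. EE 3 and EE 4 also had the highest Wnt list medians (0.54 and 0.91). A difference in tissue between the pieces therefore stays open for these genes as well and was not tested. If the animals differ in background, EE 3 and EE 4 may share a stretch that the other 6 libraries lack, and housing and background are then partly mixed in these 8 libraries.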
